A study of Mus musculus with 12 samples.

How the data were processed

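Gene expression was measured by RNA sequencing of polyadenylated RNA from immortalised mouse embryonic fibroblasts, sequenced on a BGISEQ-500 instrument per the labels. Per the labels, CBP and p300 were depleted by 4-hydroxytamoxifen in cells with floxed alleles and an inducible Cre recombinase, and cells were grown in DMEM with 10% fetal bovine serum with DMSO or with 30 µg/ml doxycycline for 24 hours. Whether the WT cells were given 4-hydroxytamoxifen or came from the same stock is not given in the sources used here. The deposited table holds raw read counts per gene for 12 libraries in 4 groups of 3. Per the submitters' processing notes the tools were STAR 2.6.0a and HTSeq 0.10.0 with genome build GRCm38.p6, and their roles and the strand of counting were not given. The table lists 12637 genes, and each reaches at least 1.03 CPM of all reads in at least 1 library, so genes with low counts had been left out before by a rule that is not stated.

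Reads counted in genes came to 44476039 to 52173143 per library. The table also has 4 sums of reads not assigned to a gene, which were left out of library sizes and tests. They held 1.85 to 7.63% of all reads as unmapped, 5.41 to 6.57% as multimapping, 4.05 to 5.01% as outside genes and 4.86 to 5.29% as ambiguous. Mitochondrially encoded genes took 3.44 to 4.05% of the gene counts and the 10 highest genes 5.14 to 5.63%. At this depth a floor of 3 counts per library was used where a group had no counts, and such floors cover counting error alone.

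Groups, the main test, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. All 12 libraries entered 1 edgeR 4.0.16 fit (R 4.3.3) of 4 group means, with TMM scaling, robust quasi-likelihood dispersions and the quasi-likelihood F test. The 5 contrasts were doxycycline against DMSO in WT and in KO, their difference (the interaction) and KO against WT with DMSO and with doxycycline. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes of a contrast, and counts at a fold of at least 2 are given beside. The SE given for a log2 fold change is its size divided by the square root of the F statistic of that test. It is thus derived from the test, and it can understate the error of a large difference in which 1 group has few counts. The low-count filter of edgeR removed no gene. Gene positions and types came from an annotation of GRCm38, in which 12628 gene identifiers were found.

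There were 32 gene lists, of which 28 had at least 5 measured members and were tested in each contrast with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the lists of a contrast. Of the 140 list tests 69 passed, and 30 of these also passed with an estimated correlation. Mean, median and test had the same sign in all 69, and their signs differed in 15 tests that did not pass. The lists covered the UPRmt, the integrated stress response, serine and one-carbon metabolism, aminoacyl-tRNA synthetases, the respiratory chain, ribosomal proteins, glycolysis, cholesterol, stress responses, the cell cycle, inflammation, interferon, immediate-early genes, TGF-beta and YAP targets, matrix, matrix-degrading enzymes, lysosome, metals, HOX genes, acetyltransferases, and markers of macrophage, endothelial, epithelial, muscle, neural and adipocyte cells.

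Named genes are Crebbp and Ep300 and, in each contrast, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change among those with a mean log2 CPM of at least 3, groups that do not overlap and an approved-style symbol. For each list up to 3 called members with the smallest p and up to 2 members that did not pass, with the highest mean log2 CPM, may also be named, and the text gives part of these. For 3 against 3 libraries, chance alone makes groups non-overlapping for 10% of genes.

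The test was checked on counts simulated from these libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. For doxycycline in WT it called 93% and 96% of them and 10 of 12437 unchanged genes. For KO it called 97% and 100% with 15 false calls, for the interaction 87% and 95% with 18, for KO against WT with DMSO 94% and 94% with 13, and with doxycycline 93% and 100% with 11. In camera a list shifted by 0.3 passed and 0 of 27 other lists did in this simulation. Genes were drawn independently of each other there, so it does not check calls of lists whose members are correlated. No difference between sets of libraries was simulated, so false calls from such a difference were not checked either.

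The alternatives fixed at the start were median-ratio scaling, no TMM, mitochondrial genes removed, a stricter filter of 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, a replicate block, a threshold at 2-fold, camera with an estimated correlation, and each library left out in turn. After the data were seen, a term for the 4 libraries with low processed pseudogenes, leaving out the KO DMSO libraries with a high unmapped share, protein-coding genes only, and removal of GC content and length trends were added. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.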

Results

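Messenger RNA was sequenced from immortalised mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos. The study compared wild-type cells (WT) with cells depleted of CBP and p300 (KO), a pair of related lysine acetyltransferases that act as transcriptional coactivators and are encoded by Crebbp and Ep300. Each genotype was given either the solvent DMSO or 30 µg/ml doxycycline (Dox) for 24 hours. Doxycycline is an antibiotic that also blocks the ribosomes of mitochondria. The 4 groups held 3 libraries each. Between 44476039 and 52173143 reads per library were counted, over 12637 genes. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The biological coefficient of variation shared by all genes was 2.26%.

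Genotype separated the libraries far more than doxycycline. The first principal component of log2 CPM (counts scaled to a common library size) held 95.0% of the variance and split KO from WT, and the second held 2.63%. Libraries also differed within 1 group. KO DMSO replicate 1 scored -14.1 on the second component, against -1.64 and -1.70 in KO DMSO replicates 2 and 3. Processed pseudogenes, which are reverse-transcribed copies of other genes, were low in KO DMSO replicate 1 and in all 3 WT DMSO libraries. Averaged over 256 such genes, log2 CPM in KO DMSO replicate 1 lay at -0.62 from the KO mean, while replicates 2 and 3 lay at 0.15 and 0.10. These 4 libraries are called the low-pseudogene set here, and values from a model with a term for the set are given beside the affected results. All 3 WT DMSO libraries and no WT Dox library were in the set, so no doxycycline comparison of WT cells within the set could be made.

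**Figure D1:**
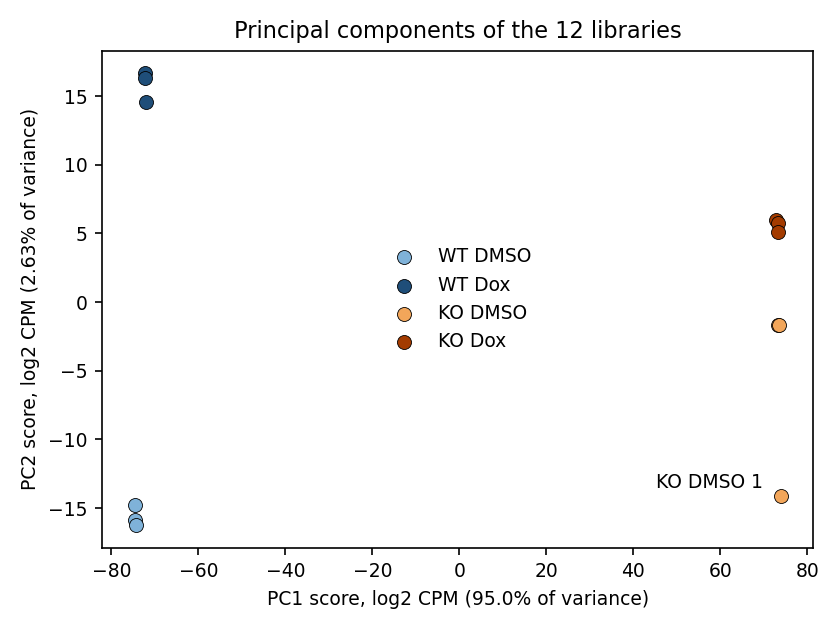
Scores of the 12 libraries on the first 2 principal components of log2 CPM, 1 point per library, coloured by group. WT and KO lie at opposite ends of the first component (95.0% of variance), and KO DMSO replicate 1 lies at -14.1 on the second (2.63%), near the WT DMSO libraries on that axis.

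**Figure D2:**
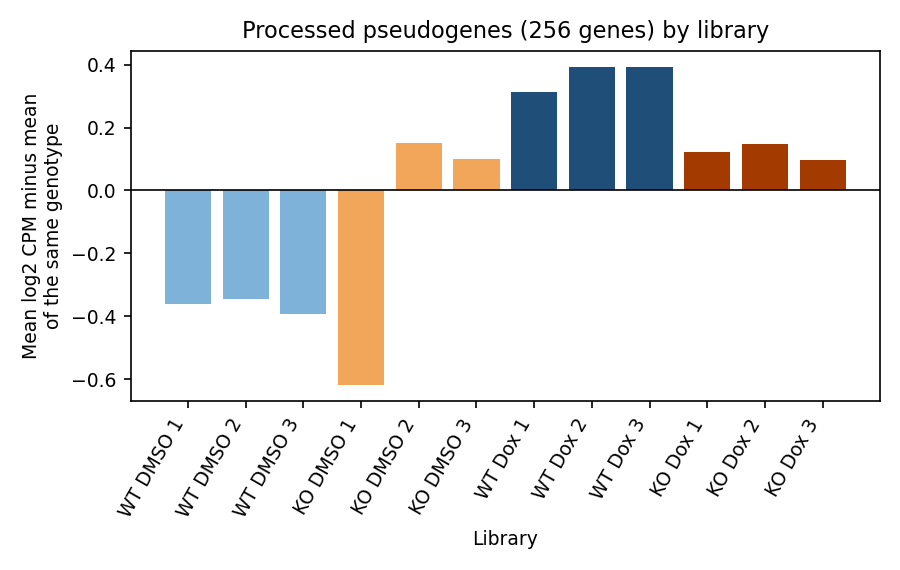
Mean log2 CPM of 256 processed pseudogenes in each library minus the mean of the 6 libraries of the same genotype, 1 bar per library, coloured by group. The 4 lowest libraries are the 3 WT DMSO libraries, between -0.39 and -0.35, and KO DMSO replicate 1 at -0.62.

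The targeted genes were both detected in every library. Crebbp (ENSMUSG00000022521, chromosome 16, positions 4081328 to 4213997 of GRCm38) had 65.8 to 67.8 CPM in the 3 WT DMSO libraries, 60.4 to 63.5 in WT Dox, 58.8 to 60.4 in KO DMSO and 53.7 to 57.0 in KO Dox. Ep300 (ENSMUSG00000055024, chromosome 15, positions 81585351 to 81652077) had 192 to 200.4 CPM in WT DMSO, 178 to 196 in WT Dox, 120.0 to 128 in KO DMSO and 111 to 115 in KO Dox. With DMSO, Ep300 was lower in KO by a log2 fold change of -0.67 ± 0.0328 (SE, n = 3 and 3; adjusted p = 3.9e-14, edgeR), and Crebbp by -0.16 ± 0.0291 (adjusted p = 2.4e-05, edgeR). The values with Dox were -0.71 ± 0.0330 for Ep300 and -0.15 ± 0.0293 for Crebbp. Without TMM scaling the Crebbp difference did not pass in either condition, at -0.01 and -0.02. Counts over a whole gene include exons outside the floxed part, so they do not check the deletion. Both genes fell slightly with doxycycline, Crebbp by 0.11 on the log2 scale in WT and in KO and Ep300 by 0.09 in WT and 0.13 in KO. Each of these 4 calls was lost in an alternative. With the set term Crebbp in WT was at -0.09, Ep300 in WT at -0.02 and Ep300 in KO at -0.10, and without KO DMSO replicate 1 Crebbp and Ep300 in KO were both at -0.09, so that only Ep300 in WT became much smaller.

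In WT cells doxycycline raised the genes of the integrated stress response, the programme driven by the transcription factor ATF4 when translation or amino acid supply is disturbed. Among genes with a mean log2 CPM of at least 3 and an approved symbol, the largest rise was that of Trib3, a pseudokinase gene induced by ATF4 (chromosome 2, positions 152337422 to 152344032), which rose from 12.5 ± 0.905 to 101 ± 2.25 CPM (SD, n = 3 each), a log2 fold change of 3.01 ± 0.0436 (SE, n = 3 and 3). Chac1, which degrades glutathione (chromosome 2, positions 119351229 to 119354381), rose by 2.22 ± 0.0426, and Cth, a cysteine synthesis enzyme, rose by 1.71 ± 0.0293. Genes for serine and mitochondrial one-carbon metabolism and for cytosolic aminoacyl-tRNA synthetases rose with them. Genes of cholesterol synthesis fell, as did 20 of 24 NF-kappa B inflammatory genes (adjusted p = 0.052 with an estimated correlation for that list).

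Of 24 measured members of the ATF4 and integrated stress response list, 21 rose (12 of them at least 2-fold), 1 fell and 2 did not pass, and 22 rose and 1 fell when adjusted over the list alone. The list mean was 1.02 (camera adjusted p = 5.5e-20). Besides Trib3, Chac1 and Cth, the stress protein gene Nupr1 rose by 1.51 ± 0.0568, the cystine transporter gene Slc7a11 by 1.27 ± 0.0637 and Sesn2, an inhibitor of mTORC1 signalling, by 1.26 ± 0.0321. Atf3, a transcription factor gene of the same response, was at 0.18 ± 0.0769 and did not pass (adjusted p = 0.059, edgeR), although it did at 0.21 without WT Dox replicate 2 (adjusted p = 0.045, edgeR), at 0.19 without KO DMSO replicates 1 and 2 (adjusted p = 0.046, edgeR) and at 0.18 among protein-coding genes only (adjusted p = 0.047, edgeR). Of 18 serine and one-carbon genes 15 rose (6 at least 2-fold) and 2 fell, or 16 and 2 adjusted over the list alone, with a mean of 0.68 (camera adjusted p = 1.7e-11). Among them, Aldh1l2 and Mthfd2, enzymes of the mitochondrial folate pathway, rose by 1.5 ± 0.0280 and 1.09 ± 0.0222. Of 20 aminoacyl-tRNA synthetase genes 19 rose and 1 fell, the same counts as adjusted over the list alone, with a mean of 0.45 (camera adjusted p = 3.5e-15). Tars, Nars and Lars, which charge the tRNAs of threonine, asparagine and leucine, rose by 0.79 ± 0.0203, 0.78 ± 0.0214 and 0.68 ± 0.0207.

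Of 24 chaperones and proteases of the mitochondrial unfolded protein response (UPRmt), 11 rose, 3 fell and 10 did not pass, as also when adjusted over the list alone. The mean was 0.12 (camera adjusted p = 0.0015, and adjusted p = 0.13 with an estimated correlation). The mitochondrial protease gene Lonp1 rose by 0.66 ± 0.0204 and the mitochondrial chaperone gene Hspa9 by 0.53 ± 0.0218. Of 12 mitochondrially encoded genes 8 rose (5 at least 2-fold), 1 fell and 3 did not pass, also adjusted over the list alone, with a mean of 0.87 (camera adjusted p = 0.0093, and adjusted p = 0.59 with an estimated correlation). The highly expressed mt-Co1, a subunit of cytochrome c oxidase, fell by 0.41 on the log2 scale from 11567 CPM, and mt-Cytb and mt-Nd5 were at 0.08 ± 0.0374 and 0.03 ± 0.0485 without passing, although both did without WT Dox replicate 1, at 0.12 and 0.10, and mt-Cytb also with DESeq2 (0.08), with only the groups compared (0.09) and without KO DMSO replicates 1 and 2 (0.10). The large rises were in genes with few counts, mt-Atp6 (2.19 ± 0.441, from 7.13 CPM), mt-Co2 (1.77 ± 0.382) and mt-Co3 (1.73 ± 0.329), all of which lost their calls with the set term, at 0.05, 0.05 and 0.20. With that term the list mean was 0.11 (camera adjusted p = 0.43). The call of the list was also lost when GC content and length trends were removed (mean 0.64, camera adjusted p = 0.08). Mitochondrial genes share reads with near-identical nuclear copies, so these values are uncertain. Of 75 nuclear-encoded respiratory chain genes 16 rose and 11 fell, or 15 and 8 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.11), although it did without WT Dox replicate 1 (mean 0.06, camera adjusted p = 0.0011). Atp5b, a subunit of ATP synthase, was at 0.03 ± 0.0202.

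Of 23 genes of cholesterol synthesis and uptake none rose and 21 fell, also adjusted over the list alone, with a mean of -0.22 (camera adjusted p = 2.3e-07). Tm7sf2, Nsdhl and Mvk, 3 enzymes of the pathway, fell by 0.58, 0.40 and 0.36 on the log2 scale. Of 30 genes of G2 and mitosis 29 fell, also adjusted over the list alone, with a mean of -0.21 (camera adjusted p = 2.6e-08, and adjusted p = 0.13 with an estimated correlation). Examples were Cdc20, an activator of the anaphase-promoting complex, at -0.35 ± 0.0253, and the spindle genes Kif20a and Nusap1 at -0.28 ± 0.0244 and -0.34 ± 0.0300. Of 24 NF-kappa B inflammatory genes 20 fell (1 at least 2-fold) and 3 rose, also adjusted over the list alone, with a mean of -0.44 (camera adjusted p = 2.3e-07, and adjusted p = 0.052 with an estimated correlation). The chemokine genes Cxcl5 and Ccl2 were at -0.96 ± 0.0206 and -0.48 ± 0.0225, and Ptx3, a secreted pattern recognition protein, was at -0.65 ± 0.0253. Outside the lists, Cebpd, a transcription factor gene, and Rasl11a, a small GTPase gene, fell by 1.21 and 1.18 on the log2 scale. Serpina3g, a protease inhibitor gene with close relatives in its cluster, was at -0.94 ± 0.0227 and is uncertain for that reason.

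Smaller shifts were found in other lists. Mitochondrial ribosomal proteins (35 of 74 rose, 4 fell) had a mean of 0.08 (camera adjusted p = 8.9e-05, and adjusted p = 0.47 with an estimated correlation). Cytosolic ribosomal proteins (32 of 75 rose, 1 fell) had a mean of 0.06 (camera adjusted p = 2.7e-04, and adjusted p = 0.65 with an estimated correlation), and the sign reversed when GC content and length trends were removed. Glycolysis and hypoxia-inducible genes (19 of 30 rose, 5 fell) had a mean of 0.10 (camera adjusted p = 8.0e-04, and adjusted p = 0.13 with an estimated correlation), with Ero1l, an endoplasmic reticulum oxidase gene, at 0.83 ± 0.0281. The NRF2 antioxidant list (12 of 23 rose, 3 fell) had a mean of 0.17 (camera adjusted p = 8.0e-04, and adjusted p = 0.31 with an estimated correlation), S phase genes (14 of 28 rose, 4 fell) of 0.04 (camera adjusted p = 0.019, and adjusted p = 0.24 with an estimated correlation), and HOX genes (13 of 21 fell, 1 rose) of -0.18 (camera adjusted p = 0.0093, and adjusted p = 0.26 with an estimated correlation). With the set term the calls of S phase and HOX genes were lost, at means of 0.04 and -0.12 (camera adjusted p = 0.07 and 0.11), as was that of mitochondrial ribosomal proteins when GC content and length trends were removed (mean 0.02, camera adjusted p = 0.064). Adjusted over the list alone, 33 mitochondrial ribosomal protein genes rose and 4 fell, 30 cytosolic ones rose and none fell, 22 glycolysis genes rose and 5 fell, and the counts of the NRF2, S phase and HOX lists were the same. The p53 targets did not pass as a list (camera adjusted p = 0.092): Gadd45a rose by 0.85 ± 0.0463 while Cdkn1a was at 0.02 ± 0.0215. The endoplasmic reticulum unfolded protein response did not pass either (camera adjusted p = 0.4), and its chaperone gene Hspa5 was at 0.00 ± 0.0192.

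By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6706 of 12637 genes changed in WT, 3016 rising and 3690 falling, and 202 changed at least 2-fold, 168 rising and 34 falling. Of the 168 that rose at least 2-fold, 100 were processed pseudogenes and 50 were protein-coding. With the set term 2850 genes changed, 71 of them at least 2-fold, 34 rising and 37 falling, and the median rise of the 100 pseudogenes went from 1.26 to 0.08. Among protein-coding genes alone, 79 changed at least 2-fold, 51 rising and 28 falling. The majority of falls among all called genes was not stable. The share that rose was 44.97%, or 49.81% with only the groups compared in the fit. It was 51.55 to 51.77% with each KO library left out in turn, although none of these belongs to the comparison. With each WT library left out in turn it stayed at 44.37 to 45.56%.

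**Figure D3:**
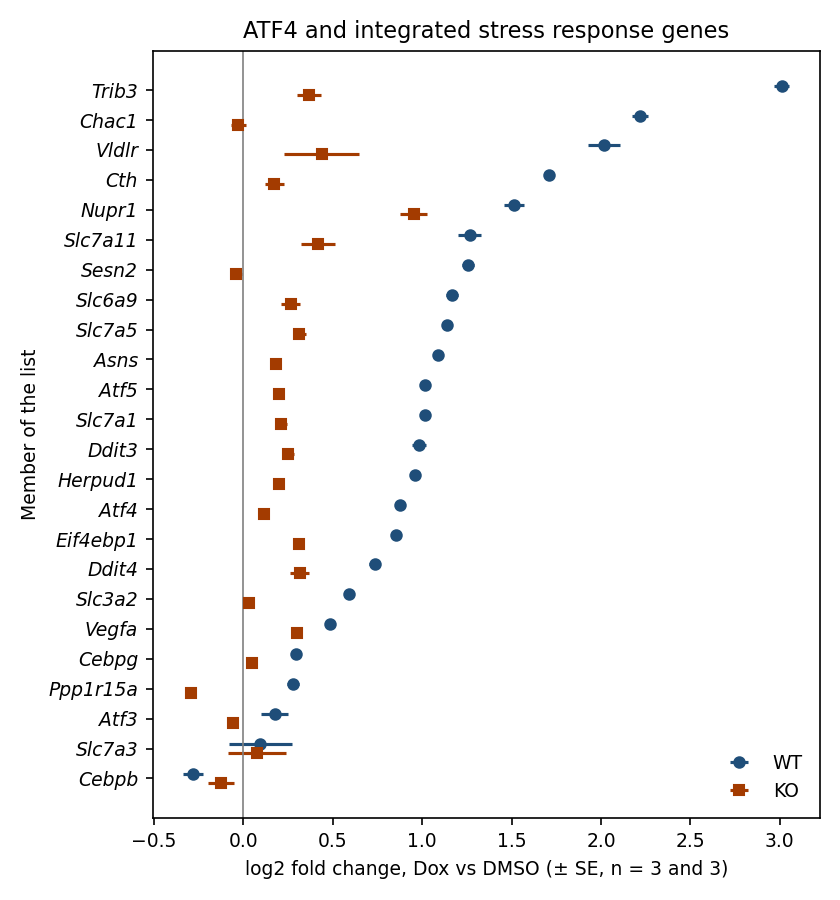
Log2 fold change with doxycycline (x axis, with standard error, n = 3 and 3) of the 24 measured genes of the ATF4 and integrated stress response list (y axis), with circles for WT and squares for KO. Trib3 lies at 3.01 in WT and 0.37 in KO.

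In KO cells doxycycline lowered the NF-kappa B inflammatory genes and raised targets of TGF-beta signalling and matrix genes. Pmepa1, a feedback inhibitor of TGF-beta signalling (chromosome 2, positions 173224458 to 173276533), rose from 15 ± 0.735 to 94.7 ± 3.70 CPM (SD, n = 3 each), a log2 fold change of 2.66 ± 0.0389 (SE, n = 3 and 3; adjusted p = 3.1e-24, edgeR). The chemokine gene Cxcl5 (chromosome 5, positions 90759360 to 90761624) fell from 11 ± 0.288 to 1.63 ± 0.127 CPM, a log2 fold change of -2.75 ± 0.0643 (adjusted p = 3.7e-20, edgeR). The integrated stress response and serine genes also rose, with mean changes of 0.19 and 0.18. Genes of cholesterol synthesis and S phase rose slightly.

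Of 24 NF-kappa B inflammatory genes 21 fell (9 at least 2-fold), none rose and 3 did not pass, and 23 fell when adjusted over the list alone. The list mean was -1.07 (camera adjusted p = 6.7e-33). Ptx3 fell by 1.99 on the log2 scale, the acute-phase genes Saa3 and Lcn2 by 1.80 and 1.64, the cytokine gene Lif by 1.49, Nfkbiz, a nuclear regulator of NF-kappa B, by 1.23 and Ccl2 by 1.17. The growth factor gene Ereg fell by 1.44. Interferon-stimulated genes fell too, 7 of 24 with none rising and 8 adjusted over the list alone, with a mean of -0.29 (camera adjusted p = 7.7e-06). Cxcl10, an interferon-induced chemokine gene, was at -0.77 ± 0.120. Of 22 TGF-beta and YAP targets 15 rose (1 at least 2-fold) and 2 fell, also adjusted over the list alone, with a mean of 0.35 (camera adjusted p = 2.2e-08). That mean was 0.22 without Tgfbi, which had no counts in KO DMSO. Among genes linked to TGF-beta, not all of them on that list, Skil and Smad7, inhibitors of SMAD signalling, rose by 1.12 ± 0.0356 and 0.56 ± 0.0337. The TGF-beta-induced transcription factor gene Klf10 rose by 1.11 ± 0.0491. Of 28 fibroblast matrix genes 20 rose and 2 fell (1 at least 2-fold), or 21 and 3 adjusted over the list alone, with a mean of 0.11 (camera adjusted p = 6.8e-12). The fibulin gene Fbln2, the collagen crosslinking enzyme gene Lox and the collagen gene Col1a1 rose by 0.81 ± 0.0225, 0.70 ± 0.0230 and 0.55 ± 0.0216.

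Of 24 integrated stress response genes 15 rose, 1 fell and 8 did not pass, also adjusted over the list alone (camera adjusted p = 7.9e-08). Nupr1 rose by 0.95 ± 0.0768, the growth factor gene Vegfa by 0.30 ± 0.0286 and the translation inhibitor gene Eif4ebp1 by 0.31 ± 0.0297. Of 18 serine and one-carbon genes 12 rose and 1 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 5.2e-07), with Phgdh, which opens serine synthesis, at 0.36 ± 0.0258 and Aldh1l2 at 0.60 ± 0.0468. Of 20 aminoacyl-tRNA synthetase genes 13 rose, also adjusted over the list alone, with a mean of 0.07 (camera adjusted p = 1.1e-05, and adjusted p = 0.073 with an estimated correlation), and Tars rose by 0.18 ± 0.0214. The UPRmt list did not pass (5 of 24 rose and 3 fell, or 6 and 3 adjusted over the list alone; camera adjusted p = 0.83), and Hspa9 was at 0.02 ± 0.0220. Of 12 mitochondrially encoded genes 3 rose and 1 fell, or 3 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.27), with mt-Co1 lower at -0.29 ± 0.0236 and mt-Cytb at -0.10 ± 0.0374 without passing. The latter passed with the set term (-0.14), without KO DMSO replicate 1 (-0.13), with DESeq2 (-0.10), with only the groups compared (-0.10), without TMM scaling (-0.11) and when GC content and length trends were removed (-0.11). Of 23 cholesterol genes 16 rose and none fell, or 18 adjusted over the list alone, with a mean of 0.16 (camera adjusted p = 3.7e-11). The synthesis enzymes Fdft1 and Nsdhl rose by 0.27 ± 0.0325 and 0.26 ± 0.0328. Of 28 S phase genes 13 rose, or 18 adjusted over the list alone, with a mean of 0.10 (camera adjusted p = 2.5e-08), and the replication helicase gene Mcm5 rose by 0.18 ± 0.0253.

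Other lists moved by less. The mean was 0.06 for cytosolic heat shock genes (7 of 18 rose; camera adjusted p = 0.0011), 0.05 for the endoplasmic reticulum unfolded protein response (12 of 21 rose, 2 fell; camera adjusted p = 0.0021, and adjusted p = 0.073 with an estimated correlation) and 0.07 for G2 and mitosis (9 of 30 rose; camera adjusted p = 8.8e-04, and adjusted p = 0.29 with an estimated correlation). It was 0.05 for the nuclear-encoded respiratory chain (11 of 75 rose; camera adjusted p = 7.9e-04, and adjusted p = 0.74 with an estimated correlation), 0.03 for mitochondrial ribosomal proteins (7 of 74 rose; camera adjusted p = 0.041, and adjusted p = 0.77 with an estimated correlation) and 0.05 for glycolysis (12 of 30 rose, 1 fell; camera adjusted p = 0.011, and adjusted p = 0.19 with an estimated correlation). The call of mitochondrial ribosomal proteins was also lost with the set term (mean 0.03, camera adjusted p = 0.15), without TMM scaling (mean 0.03, camera adjusted p = 0.054) and without KO DMSO replicate 1, KO Dox replicate 1 or KO Dox replicate 2 (means 0.04, 0.03 and 0.04, camera adjusted p = 0.13, 0.17 and 0.081). When GC content and length trends were removed, the calls of both this list and the nuclear-encoded respiratory chain were lost, at means of 0.02 and 0.01 (camera adjusted p = 0.48 and 0.48). Adjusted over the list alone, 13 genes of the endoplasmic reticulum response rose and 5 fell, 12 genes of G2 and mitosis, 10 of the nuclear-encoded respiratory chain and 6 mitochondrial ribosomal protein genes rose, and the counts for heat shock and glycolysis were the same. Metal-responsive genes did not pass (4 of 14 rose, 5 fell; camera adjusted p = 0.18), and the metallothionein gene Mt1 fell by 0.68 on the log2 scale.

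In KO cells 2740 genes changed with doxycycline, 1462 rising and 1278 falling, and 30 changed at least 2-fold, 7 rising and 23 falling (edgeR). The 7 included Sparcl1, which had no counts in KO DMSO and only 0.0375 CPM in KO Dox. Without KO DMSO replicate 1 the counts of genes changed and of genes changed at least 2-fold were 2301 and 31. Without KO DMSO replicates 1 and 2, in which 7.63% and 6.65% of reads were unmapped, 1089 genes changed, 733 rising and 356 falling. The balance of directions was not stable, since 831 genes fell without KO DMSO replicate 1 (1470 rose), 766 without KO Dox replicate 1 (1130 rose) and 836 without KO Dox replicate 2 (1240 rose), and the share of called genes that rose went from 53.4% to 45.6% without TMM scaling.

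The interaction of doxycycline and genotype asks whether the response differed between KO and WT, which is the question the design puts to CBP and p300. The response of the integrated stress genes was smaller in KO. Trib3 rose from 12.5 to 101 CPM in WT and from 6.90 to 8.89 in KO, an interaction of -2.64 ± 0.0842 on the log2 scale (SE, n = 3 per group; adjusted p = 4.9e-17, edgeR). Chac1 had an interaction of -2.24 ± 0.0616, Cth of -1.54 ± 0.0628 and Sesn2 of -1.30 ± 0.0458. Genes of cholesterol synthesis, which fell in WT, did not fall in KO. Of 30 genes of G2 and mitosis 29 fell in WT (adjusted p = 0.13 with an estimated correlation for the list) and none in KO, while several inflammatory genes fell further in KO.

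Of 24 integrated stress response genes, 22 had a lower response in KO (5 by at least 2-fold) and none a higher one, also adjusted over the list alone, with a mean interaction of -0.83 (camera adjusted p = 2.3e-22). Of 18 serine and one-carbon genes 15 had a lower (2 by at least 2-fold) and 2 a higher response, also adjusted over the list alone, with a mean of -0.50 (camera adjusted p = 6.9e-12). Mthfd2 was at -0.81 ± 0.0338 and the serine synthesis enzyme gene Psat1 at -0.69 ± 0.0350. Of 20 aminoacyl-tRNA synthetase genes 18 had a lower response, or 19 adjusted over the list alone, with a mean of -0.38 (camera adjusted p = 1.7e-16), and Nars and Tars were at -0.67 ± 0.0304 and -0.61 ± 0.0295. In the UPRmt list 9 of 24 genes had a lower and 2 a higher response, or 10 and 2 adjusted over the list alone, with a mean of -0.11 (camera adjusted p = 0.002, and adjusted p = 0.13 with an estimated correlation). Lonp1 was at -0.69 ± 0.0288 and Hspa9 at -0.51 ± 0.0309. The mitochondrially encoded list did not pass (mean -0.57, camera adjusted p = 0.1), although it did without KO DMSO replicate 1 (mean -0.76, camera adjusted p = 5.3e-05) and without WT Dox replicate 1 (mean -0.62, camera adjusted p = 0.038). Its mean interaction was 0.01 with the set term (camera adjusted p = 0.76). In that list mt-Co1 was at 0.12 ± 0.0333 (adjusted p = 0.0075, edgeR), or 0.08 and not passing without KO DMSO replicates 1 and 2. Crebbp and Ep300 were at 0.01 ± 0.0413 and -0.04 ± 0.0465 without passing.

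All 23 cholesterol genes had a higher response in KO, also adjusted over the list alone, with a mean interaction of 0.38 (camera adjusted p = 2.2e-15), and Tm7sf2 and Nsdhl were at 0.85 ± 0.0579 and 0.66 ± 0.0450. All 30 genes of G2 and mitosis had a higher response in KO, also adjusted over the list alone, with a mean of 0.27 (camera adjusted p = 1.4e-12). The mitotic kinesin gene Kif20a was at 0.35 ± 0.0396 and the spindle checkpoint gene Bub1b at 0.29 ± 0.0352. Of 24 NF-kappa B genes 17 had a lower response in KO (8 by at least 2-fold) and 3 a higher one, also adjusted over the list alone, with a mean of -0.63 (camera adjusted p = 5.4e-09). Cxcl5, Saa3, Ptx3 and Lcn2 were at -1.79 ± 0.0711, -1.71 ± 0.0979, -1.33 ± 0.0413 and -1.19 ± 0.0317, and Ereg was at -1.34 ± 0.0405. Of 22 TGF-beta and YAP targets 14 had a higher and 2 a lower response, or 15 and 2 adjusted over the list alone, with a mean of 0.36 (camera adjusted p = 1.1e-07), which was 0.24 without Tgfbi. Of 28 matrix genes 17 had a higher response, or 18 adjusted over the list alone, with a mean of 0.13 (camera adjusted p = 6.7e-07).

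Single genes showed the same split. Pmepa1 had an interaction of 1.75 ± 0.0542, the SMAD transcription factor gene Smad9 of 1.59 ± 0.0895 and the sphingosine kinase gene Sphk1 of 1.15 ± 0.0390. The smooth muscle actin gene Acta2 was at 0.83 ± 0.0538, the matricellular gene Thbs1 at 0.66 ± 0.0343, the mesenchymal transcription factor gene Prrx1 at 0.61 ± 0.0352, Fbln2 at 0.50 ± 0.0302 and Col1a1 at 0.47 ± 0.0297. The coagulation initiator gene F3 was at -0.60 ± 0.0480. Lists with small mean interactions were mitochondrial ribosomal proteins at -0.05 (20 of 74 lower, 4 higher; camera adjusted p = 0.014, and adjusted p = 0.63 with an estimated correlation) and cytosolic ribosomal proteins at -0.06 (13 of 75 lower; camera adjusted p = 5.7e-04, and adjusted p = 0.65 with an estimated correlation), whose sign reversed when GC content and length trends were removed. The NRF2 list was at -0.12 (11 of 23 lower, 3 higher; camera adjusted p = 0.0033, and adjusted p = 0.37 with an estimated correlation) and HOX genes at 0.18 (11 of 21 higher, 2 lower; camera adjusted p = 0.029, and adjusted p = 0.3 with an estimated correlation). Adjusted over the list alone, 10 cytosolic ribosomal protein genes were lower, 13 HOX genes higher and 2 lower, and the counts of the mitochondrial ribosomal protein and NRF2 lists were the same. With the set term the calls of mitochondrial ribosomal proteins and HOX genes were lost, at means of -0.03 and 0.14 (camera adjusted p = 0.078 and 0.078), and also when GC content and length trends were removed, at means of 0.00 and 0.18 (camera adjusted p = 0.18 and 0.086). The call of mitochondrial ribosomal proteins was also lost without WT Dox replicate 2 or KO Dox replicate 3 (means -0.03 and -0.05, camera adjusted p = 0.081 and 0.071), and that of HOX genes without WT Dox replicate 1 (mean 0.16, camera adjusted p = 0.077). The interferon-stimulated genes did not pass, at a mean of -0.28 (camera adjusted p = 0.058), but did with the set term (mean -0.33, camera adjusted p = 0.039), with median-ratio scaling (camera adjusted p = 0.0495) and without WT DMSO replicate 1, WT Dox replicate 2, KO Dox replicate 1 or KO Dox replicate 2, with the lowest p without KO Dox replicate 2 (mean -0.34, camera adjusted p = 0.03).

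The interaction passed for 4107 genes, 2295 with a higher and 1812 with a lower response in KO, and for 107 by at least 2-fold, 30 higher and 77 lower (edgeR). The 30 included Sparcl1, which had no counts in KO DMSO and only 0.0375 CPM in KO Dox. Of the 77, 33 were processed pseudogenes. With the set term 2865 genes passed and 56 by at least 2-fold (23 higher, 33 lower), and without KO DMSO replicate 1 these counts were 4095 and 191 (31 higher, 160 lower). Among protein-coding genes alone 68 passed by at least 2-fold (28 higher, 40 lower). The majority direction among all called genes was not stable. The share with a higher response in KO was 55.9%, or 49.5% without TMM scaling and 49.1% without KO DMSO replicate 2. Across all 12637 genes, which are not independent replicates, the log2 fold changes with doxycycline in WT and KO had Pearson's r = 0.349 and Spearman's rho = 0.344, and 62.8% had the same sign. The value of r was 0.229 without KO DMSO replicate 1 and 0.181 without KO DMSO replicates 1 and 2. The responses of WT and KO shared no libraries. There were 683 genes that rose in both genotypes, against 348.9 for independent lists, and 720 that fell in both, against 373.2. The 50 protein-coding genes that rose at least 2-fold in WT had a median log2 fold change of 1.26 in WT and 0.27 in KO, or 1.07 and 0.17 with the set term. Of these, 21 rose and 1 fell in KO, and 36 had a lower response in KO by the interaction (30 with the set term), a count that rests partly on the WT libraries used to choose them. Of the 100 processed pseudogenes that rose as much, 51 had a lower response in KO, and 2 with the set term.

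**Figure D4:**
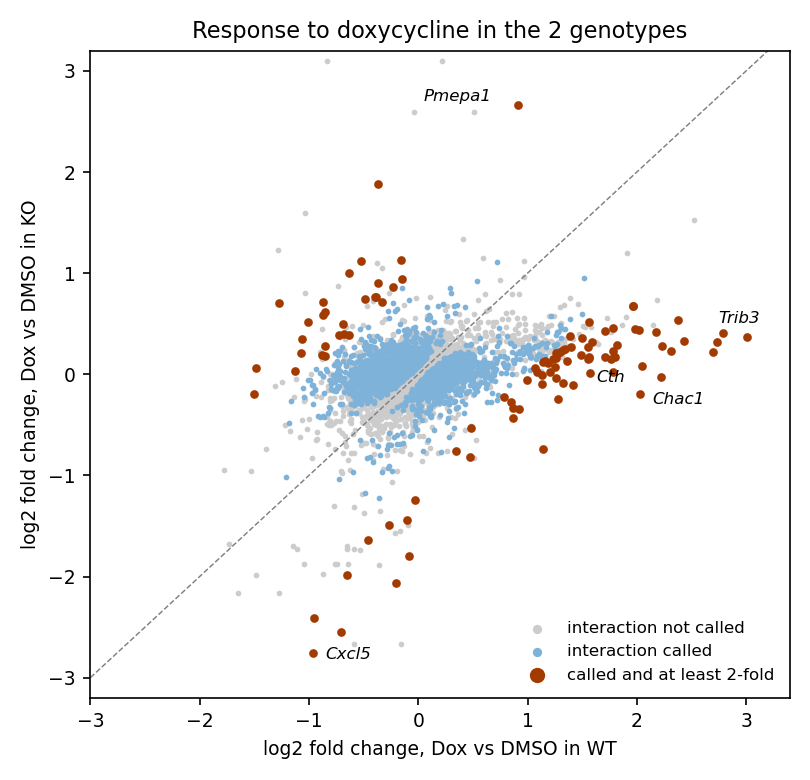
Log2 fold change with doxycycline in WT (x axis) and in KO (y axis), 1 point per gene, with the line of equal response dashed and the interaction call shown by colour; 4 of 12637 genes lie outside the axes. Trib3 and Chac1 lie far right near the horizontal, and Pmepa1 and Cxcl5 lie at 2.66 and -2.75 in KO.

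With DMSO alone, KO cells differed from WT cells in most measured genes, a comparison that bears on what the loss of CBP and p300 does to the resting transcriptome. The matricellular genes Ctgf (chromosome 10, positions 24595442 to 24598683) and Cyr61, targets of YAP, were higher in KO, with Ctgf at 1698 ± 19.8 CPM against 28.5 ± 1.38 in WT (SD, n = 3 each), a log2 fold change of 5.90 ± 0.0499 (SE, n = 3 and 3). Several immediate-early genes were higher as well, Atf3 by 4.84 ± 0.0448, Fos by 4.22 ± 0.0609 and Egr1 by 3.81 ± 0.0270. Genes of the fibroblast matrix were lower, with the collagen gene Col3a1 (chromosome 1, positions 45311538 to 45349706) at 1.82 ± 0.185 CPM against 823 ± 7.42, a log2 fold change of -8.82 ± 0.0409. That SE is derived from the F statistic and understates the error at so few KO counts. Genes of DNA replication and mitosis, of serine synthesis and of ribosomal proteins were also lower. Of these lists, G2 and mitosis (adjusted p = 0.066 with an estimated correlation), cytosolic ribosomal proteins (adjusted p = 0.44) and mitochondrial ribosomal proteins (adjusted p = 0.67) lost their calls with an estimated correlation.

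Of 28 fibroblast matrix genes 27 were lower in KO (23 at least 2-fold) and 1 higher, also adjusted over the list alone, with a mean of -3.11 (camera adjusted p = 1.5e-09). Lox and Fbln2 were at -3.97 ± 0.0234 and -3.87 ± 0.0234. Among secreted proteins outside the list, Wisp2, a relative of Ctgf, was at -10.33 ± 0.0663, the growth factor gene Ptn at -7.30 ± 0.0351, the WNT modulator gene Sfrp2 at -7.18 ± 0.0326, the BMP antagonist gene Grem1 at -7.06 ± 0.0388 and Serpina3g, uncertain for its close relatives, at -9.09 ± 0.0491. Of 23 matrix-degrading enzymes 18 were lower (14 at least 2-fold) and 3 higher, also adjusted over the list alone, with a mean of -1.95 (camera adjusted p = 0.0014). The protease genes Mmp9, Adamts2 and Mmp2 were at -7.37 ± 0.0739, -5.49 ± 0.0503 and -1.84 ± 0.0198. TGF-beta and YAP targets went both ways, 10 of 22 higher (8 at least 2-fold) and 12 lower (6 at least 2-fold), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.84). Its median was -0.22, also with Tgfbi, which had no counts in KO DMSO, at its bound. Cyr61 and the cardiac ankyrin repeat gene Ankrd1 were at 4.09 ± 0.0282 and 2.19 ± 0.0218. Of 28 CREB and immediate-early genes 17 were higher (10 at least 2-fold) and 11 lower (11 at least 2-fold), also adjusted over the list alone, without a call as a list (camera adjusted p = 0.47), and the nuclear receptor gene Nr4a1 and the stress-induced gene Ier3 were at 3.42 ± 0.0294 and 2.94 ± 0.0275.

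All 28 S phase genes were lower in KO (26 at least 2-fold), also adjusted over the list alone, with a mean of -1.70 (camera adjusted p = 4.5e-10). Uhrf1, which maintains DNA methylation, and the replication helicase genes Mcm7 and Mcm4 were at -2.26 ± 0.0223, -2.05 ± 0.0231 and -1.71 ± 0.0223. All 30 genes of G2 and mitosis were at least 2-fold lower, also adjusted over the list alone, with a mean of -2.13 (camera adjusted p = 6.8e-11, and adjusted p = 0.066 with an estimated correlation). The spindle genes Ckap2 and Tpx2 and Bub1b were at -2.82 ± 0.0273, -2.17 ± 0.0216 and -2.28 ± 0.0251. Of 75 cytosolic ribosomal protein genes 74 were lower (9 at least 2-fold), also adjusted over the list alone, with a mean of -0.74 (camera adjusted p = 9.4e-12, and adjusted p = 0.44 with an estimated correlation). Rpsa, Rps2 and Rpl12 were at -1.34, -1.38 and -1.40, and single ribosomal protein genes are uncertain because they share reads with their pseudogenes. Mitochondrial ribosomal proteins (54 of 74 lower, 9 higher) had a mean of -0.27 (camera adjusted p = 0.004, and adjusted p = 0.67 with an estimated correlation). Of 18 serine and one-carbon genes 17 were lower (13 at least 2-fold), also adjusted over the list alone, with a mean of -1.49 (camera adjusted p = 4.0e-06), and Phgdh, Aldh1l2 and the folate enzyme gene Mthfd1l were at -2.0 ± 0.0252, -2.38 ± 0.0391 and -2.48 ± 0.0352. Integrated stress response genes (17 of 24 lower, 5 higher) had a mean of -0.57 (camera adjusted p = 0.02, and adjusted p = 0.26 with an estimated correlation), with Eif4ebp1 and the mTORC1 inhibitor gene Ddit4 at -1.68 ± 0.0280 and -2.41 ± 0.0418. Aminoacyl-tRNA synthetases (18 of 20 lower, 2 higher) had a mean of -0.50 (camera adjusted p = 9.1e-04, and adjusted p = 0.21 with an estimated correlation).

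Of 30 lysosome and autophagy genes 27 were higher in KO (10 at least 2-fold) and 1 lower, also adjusted over the list alone, with a mean of 0.86 (camera adjusted p = 3.4e-07, and adjusted p = 0.089 with an estimated correlation). The sialidase gene Neu1, the proton pump subunit gene Atp6v0d1 and the peptidase gene Tpp1 were at 2.67 ± 0.0314, 1.53 ± 0.0246 and 1.39 ± 0.0206. Of 23 cholesterol genes 20 were lower (8 at least 2-fold) and 2 higher, also adjusted over the list alone, with a mean of -0.78 (camera adjusted p = 1.2e-04), and Insig1, a sterol sensor, and the synthesis enzyme gene Sqle were at -2.01 ± 0.0303 and -1.15 ± 0.0208. Glycolysis and hypoxia-inducible genes (20 of 30 lower, 5 higher) had a mean of -0.64 (camera adjusted p = 0.021, and adjusted p = 0.26 with an estimated correlation). The NF-kappa B list did not pass (16 of 24 lower, 8 higher; camera adjusted p = 0.094, or 0.043 without TMM scaling), although Cxcl5 and the chemokine gene Ccl7 were lower at -6.76 ± 0.0302 and -5.21 ± 0.0354. NRF2 genes did not pass (camera adjusted p = 0.37), with the ferritin gene Fth1, uncertain for its pseudogenes, at -2.31 ± 0.0250. Histone acetyltransferase and bromodomain genes did not pass (15 of 24 higher and 8 lower, or 16 and 8 adjusted over the list alone; camera adjusted p = 0.36), with Kat2b, a lysine acetyltransferase gene, at 2.23 ± 0.0300. HOX genes, heat shock genes and interferon-stimulated genes did not pass (camera adjusted p = 0.81, 0.84 and 0.73), and Hoxb9, a positional identity gene, was at 2.64 ± 0.0251. The mitochondrially encoded list did not pass (9 of 12 higher, 1 lower; mean 0.63, camera adjusted p = 0.2), although it did without KO DMSO replicate 1 (mean 0.80, camera adjusted p = 0.018). Its mean was 0.05 with the set term (camera adjusted p = 0.84).

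Markers of other cell types went both ways, with more of them lower than higher in KO. Of 4 measured macrophage markers, the lysosomal glycoprotein gene Cd68 was higher in KO at 4.02 ± 0.0770 and the lysozyme gene Lyz2 lower at -2.11 ± 0.0678, and Csf1r and Cd14 were lower at -0.51 and -0.54. Of 3 endothelial markers Egfl7 and Flt1 were lower (-1.74 and -1.26) and Eng was at -0.14 without passing. Of 3 muscle markers Des and Ttn were lower (-2.18 and -0.85) and Tnnc1 higher (0.59), and the 1 measured epithelial marker, Krt7, was higher at 1.52. These 4 short lists were not tested as lists, and Csf1r, outside the rule for named genes, was named after its value was seen to complete the list. Neural markers (5 of 6 lower, 4 at least 2-fold, also adjusted over the list alone) had a mean of -2.09 (camera adjusted p = 0.033, and adjusted p = 0.13 with an estimated correlation), with the tubulin gene Tubb3 at -5.37 ± 0.0869. Adipocyte markers (3 of 7 higher, 4 lower) did not pass (camera adjusted p = 0.81), with the lipid carrier gene Fabp4 at -6.75 ± 0.0737.

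In all, 11296 of 12637 genes differed between KO and WT with DMSO, 5699 higher and 5597 lower, and 3473 differed at least 2-fold, 1368 higher and 2105 lower (edgeR). Without TMM scaling the median log2 fold change of all genes was 0.17 with DMSO and 0.14 with Dox, so directions of small differences between the genotypes hold relative to that shift. Except for the acetyltransferase and bromodomain list with DMSO, the counts of list members higher and lower in KO were the same when adjusted over the list alone, with DMSO and with Dox.

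The difference between genotypes was asked again in the presence of doxycycline, in 6 libraries that all lay outside the low-pseudogene set. Ctgf, Cyr61 and Egr1 were higher in KO at 5.54 ± 0.0480, 4.50 ± 0.0288 and 3.85 ± 0.0272 (SE, n = 3 and 3), and the growth factor gene Hbegf was at 3.68 ± 0.0274. Col3a1 and Wisp2 were lower at -8.76 ± 0.0401 and -9.50 ± 0.0614, Xdh, a purine catabolism gene, at -7.33 ± 0.0595 and Cxcl5 at -8.56 ± 0.0390 (adjusted p = 5.5e-36, edgeR). The integrated stress response and serine genes lay further below WT than with DMSO, as the interaction gives. The difference of the integrated stress response list with Dox had an adjusted p = 0.066 with an estimated correlation.

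Of 24 integrated stress response genes 20 were lower (17 at least 2-fold) and 3 higher, also adjusted over the list alone, with a mean of -1.40 (camera adjusted p = 7.4e-05, and adjusted p = 0.066 with an estimated correlation), and Cth was at -3.70 ± 0.0361. All 18 serine and one-carbon genes were lower (15 at least 2-fold), also adjusted over the list alone, with a mean of -1.99 (camera adjusted p = 2.1e-07), and Aldh1l2 and Mthfd2 were at -3.28 ± 0.0329 and -2.13 ± 0.0235. Aminoacyl-tRNA synthetases (19 of 20 lower, 10 at least 2-fold) had a mean of -0.87 (camera adjusted p = 6.9e-06, and adjusted p = 0.077 with an estimated correlation), with Lars at -1.60 ± 0.0214. Matrix genes (26 of 28 lower, 2 higher) had a mean of -2.98 (camera adjusted p = 1.3e-08), matrix-degrading enzymes (19 of 23 lower, 4 higher) of -2.19 (camera adjusted p = 0.0012) and S phase genes (28 of 28 lower) of -1.64 (camera adjusted p = 6.3e-10). G2 and mitosis genes (30 of 30 lower) had a mean of -1.86 (camera adjusted p = 2.2e-10, and adjusted p = 0.066 with an estimated correlation), cytosolic ribosomal proteins (75 of 75 lower) of -0.80 (camera adjusted p = 1.3e-12, and adjusted p = 0.38 with an estimated correlation) and lysosome genes (28 of 30 higher, 1 lower) of 0.86 (camera adjusted p = 1.1e-07, and adjusted p = 0.066 with an estimated correlation). Uhrf1, Ckap2, Rpsa and Neu1 were at -2.13 ± 0.0219, -2.63 ± 0.0274, -1.36 ± 0.0227 and 2.72 ± 0.0314. NF-kappa B genes (17 of 24 lower, 6 higher) had a mean of -2.22 (camera adjusted p = 0.0087, and adjusted p = 0.23 with an estimated correlation), with Ptx3 at -3.70 ± 0.0315. Cholesterol genes (18 of 23 lower, 3 higher) had a mean of -0.39 (camera adjusted p = 0.0093, and adjusted p = 0.066 with an estimated correlation). The mitochondrially encoded list did not pass (camera adjusted p = 0.59), with mt-Co1 higher at 0.22 ± 0.0236.

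With Dox 11363 genes differed between KO and WT, 5701 higher and 5662 lower, and 3471 differed at least 2-fold, 1371 higher and 2100 lower (edgeR). Across genes the log2 fold changes between genotypes with DMSO and with Dox had r = 0.977, and 3088 genes differed at least 2-fold in the same direction in both conditions, which share no libraries.

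**Figure D5:**
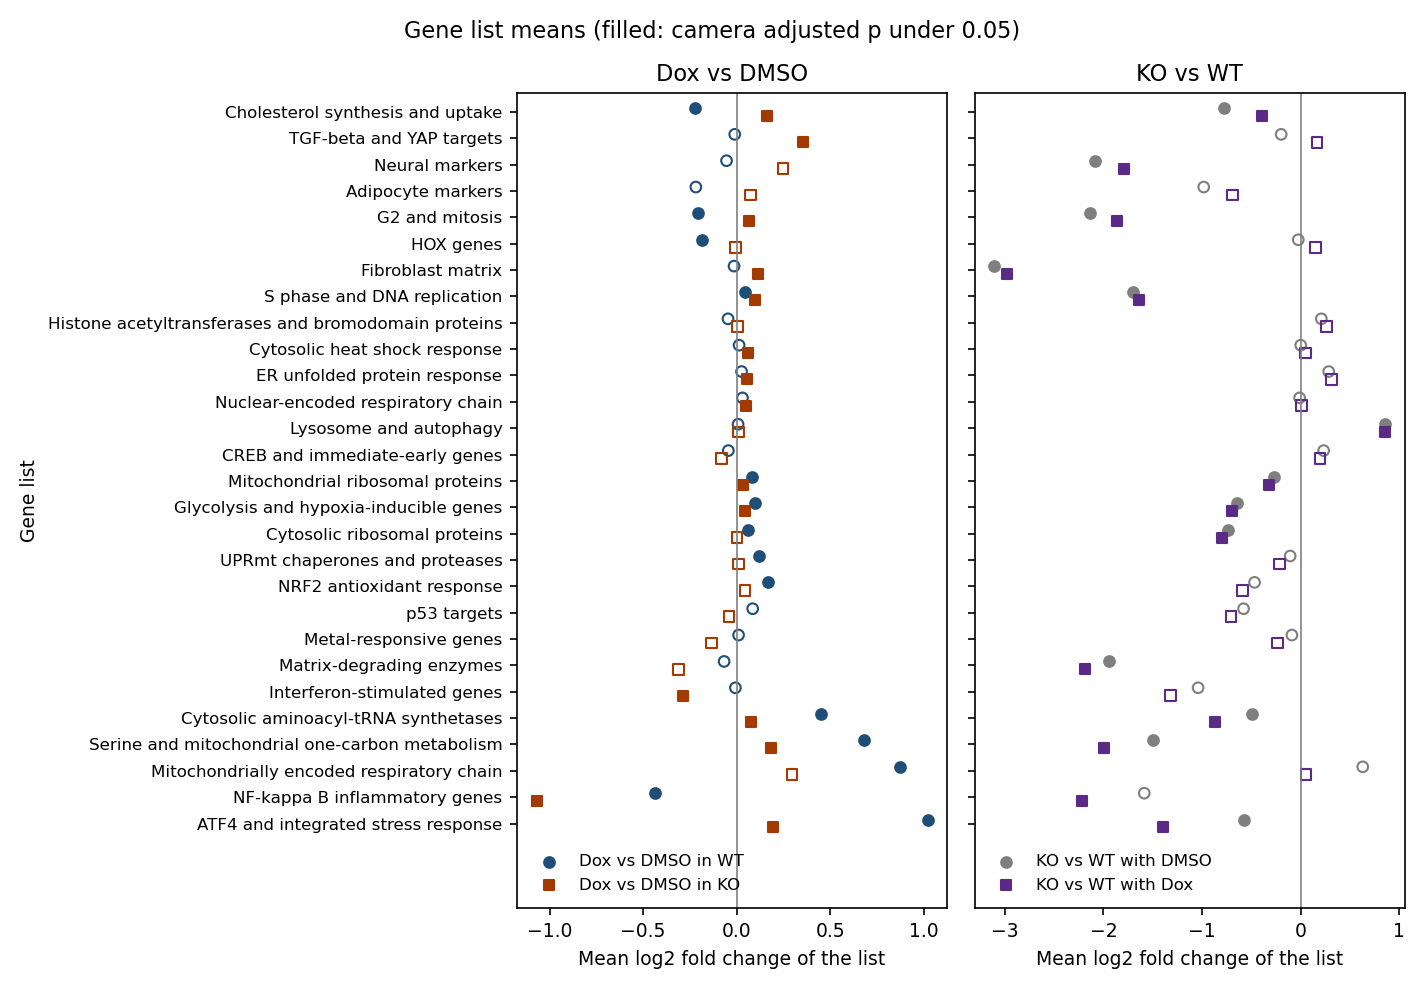
Mean log2 fold change (x axis) of the 28 tested gene lists (y axis), in the left panel for doxycycline against DMSO in WT (circles) and KO (squares), in the right panel for KO against WT with DMSO (circles) and with Dox (squares). Filled symbols mark a camera adjusted p under 0.05, and the integrated stress response list lies at 1.02 in WT and 0.19 in KO.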

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

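The tests of the processed pseudogenes, of the difference between KO and WT and of the smaller response of the ATF4 list were chosen after the results were seen, and the criteria for the splits of the libraries were also written down after their counts had been seen, whereas the interaction test was planned. The interaction test separated the doxycycline responses of KO and WT for 4107 genes, 107 of them by at least 2-fold, or 56 with a term for the 4 libraries low in processed pseudogenes. Of the 100 splits of treatment labels within genotypes, 1, the real one, gave as many genes, and the highest of the others gave 3905. Mixing the labels also removes the response within each genotype, and the splits with the highest counts kept the WT labels, so these splits do not test the interaction. For the other 4 comparisons the splits are too few for a share under 0.05. Their real counts were 6706 for doxycycline in WT, 2740 in KO, 11296 for KO against WT with DMSO and 11363 with Dox. In each of them 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0 by edgeR after adjustment and 1235, 591, 123 and 109 at an unadjusted p under 0.05.

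Gene lists whose mean response differed between genotypes by the interaction test were the integrated stress response (-0.83), serine and one-carbon metabolism (-0.50), aminoacyl-tRNA synthetases (-0.38) and NF-kappa B genes (-0.63), all lower in KO. Cholesterol (0.38), G2 and mitosis (0.27), TGF-beta and YAP targets (0.36, or 0.24 without Tgfbi) and matrix genes (0.13) were higher in KO. The calls of 5 further lists were lost with an estimated correlation. These were the UPRmt (-0.11, adjusted p = 0.13 with an estimated correlation), mitochondrial ribosomal proteins (-0.0453, adjusted p = 0.63), cytosolic ribosomal proteins (-0.0599, adjusted p = 0.65), NRF2 genes (-0.12, adjusted p = 0.37) and HOX genes (0.18, adjusted p = 0.3). The calls of mitochondrial ribosomal proteins and HOX genes were also lost with a term for the 4 libraries low in processed pseudogenes (means -0.03 and 0.14, camera adjusted p = 0.078 and 0.078) and with GC content and length trends removed (means 0.00 and 0.18, camera adjusted p = 0.18 and 0.086). The first was lost without WT Dox replicate 2 or KO Dox replicate 3 (means -0.03 and -0.05, camera adjusted p = 0.081 and 0.071) and the second without WT Dox replicate 1 (mean 0.16, camera adjusted p = 0.077). Of these means only that of mitochondrial ribosomal proteins with GC content and length trends removed lay near 0. Removing GC content and length trends turned the sign of the cytosolic ribosomal proteins, to 0.0156. Among named genes the same test separated Trib3 (-2.64), Chac1 (-2.24), Cth (-1.54), Sesn2 (-1.30), Mthfd2 (-0.81), Psat1 (-0.69), Nars (-0.67), Tars (-0.61), Lonp1 (-0.69) and Hspa9 (-0.51), all lower in KO. It also separated the inflammatory and growth factor genes Lcn2 (-1.19), Ptx3 (-1.33), Cxcl5 (-1.79), Saa3 (-1.71) and Ereg (-1.34), and F3 (-0.60). Those with a higher response in KO were Pmepa1 (1.75), Smad9 (1.59), Sphk1 (1.15), Thbs1 (0.66), Acta2 (0.83), Prrx1 (0.61), Fbln2 (0.50), Col1a1 (0.47), Tm7sf2 (0.85), Nsdhl (0.66), Kif20a (0.35), Bub1b (0.29) and mt-Co1 (0.12, or 0.08 and not passing without KO DMSO replicates 1 and 2).

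Reads that no comparison used also stood out. The share of reads not mapped was 7.63% in KO DMSO replicate 1 and 6.65% in KO DMSO replicate 2, against at most 2.06% in the WT DMSO libraries. That of WT Dox replicate 2, at 2.09%, lay only just above this maximum and did not stand apart.

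Of the 168 genes that rose at least 2-fold with doxycycline in WT, 100 were processed pseudogenes. A difference between sets of libraries is a candidate explanation: the median of these 100 genes in KO DMSO replicate 1 was -1.21 from the mean of replicates 2 and 3, on the log2 scale, and all 100 were lower there. The set of 4 libraries was defined from the levels of processed pseudogenes, so that value is not independent of it. A rise with doxycycline in both genotypes was argued against by a median of -0.0198 (SD 0.155 across the 100 genes) for KO Dox minus KO DMSO replicates 2 and 3. A rise in WT alone stays open, because all WT DMSO libraries and no WT Dox library lay in the set.

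KO and WT differed across the transcriptome. The library set as the cause was argued against by the 6 libraries with doxycycline, none of which lay in the set, where fold changes between genotypes had r = 0.977 with those found with DMSO, and 3471 against 3473 genes differed at least 2-fold. Gain or loss of a whole chromosome in 1 line was argued against by the medians of 20 chromosomes with DMSO, of which the farthest from 0 was -0.11. Cells of another origin under either label cannot be told apart from the deletion, since Crebbp was at -0.16 over the whole gene, which includes exons outside the deleted part. The loss of CBP and p300, 4-hydroxytamoxifen itself and differences between cell stocks may each contribute and stay open.

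The integrated stress response list answered doxycycline less in KO than in WT. With a term for the library set the mean interaction was -0.84. The size of that term rests on KO DMSO libraries alone, since all WT DMSO libraries and no WT Dox library lay in the set. The value thus argues only against a set effect of the same size in both genotypes. An effect of the set in WT alone stays open. A weaker action of doxycycline on every responding list was argued against by the NF-kappa B list, which fell further in KO on the log2 scale, with a mean interaction of -0.63. It was the only list called in the same direction in both genotypes and called by the interaction as larger in KO. Its mean in KO against WT with DMSO was -1.59, without passing, so the fall in KO may start from a lower level. The fall of that list in WT had an adjusted p = 0.052 with an estimated correlation, while the interaction passed with it (adjusted p = 0.024). A list already raised in KO was argued against by the 22 members with a smaller response, whose median in KO against WT with DMSO was -0.85, with 16 lower and 5 higher. A part of CBP and p300 in this response is a hypothesis that these values leave possible, and a weaker action of the drug on mitochondria alone, or a difference between cell stocks, could also give it and was not tested.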

How the results depend on the processing

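The term for the low-pseudogene set, the fit without the KO DMSO libraries of high unmapped share, the fit of protein-coding genes only and the removal of GC content and length trends were chosen after seeing the data. For 171 pairs of a named gene and a comparison, under all alternatives, 3187 values kept the side of the threshold, and where called also the direction. Values not called in either fit could change sign and still be counted there. Another 21 lost the call, 15 gained one and 0 changed sign as called values. Of the values of the 28 lists 2179 were the same in this sense, 59 lost the call (39 of them with an estimated correlation), 22 gained one and 3 reversed in sign with a call in the main fit or the alternative. Means not called in either fit could change sign within the 2179. Those 3 were the cytosolic ribosomal proteins with GC content and length trends removed, at -0.055 for doxycycline in WT, -0.0394 in KO and 0.0156 for the interaction, and the cause was not tested. In KO the main mean was 0.0006 and not called (camera adjusted p = 0.83), and a call was gained (camera adjusted p = 0.0029). With a threshold at 2-fold the counts were 202, 30, 107, 3473 and 3471, by construction lower than 6706 for doxycycline in WT, 2740 in KO, 4107 for the interaction, 11296 for KO against WT with DMSO and 11363 with Dox. With the set term, whose size rests on KO DMSO replicate 1 against 2 and 3 alone, 2850 genes were called for WT (1267 rose, 1583 fell), 71 of them at least 2-fold (34 rose, 37 fell), 56 for the interaction at 2-fold (23 higher, 33 lower in KO), and r between the responses was 0.379. Without KO DMSO replicates 1 and 2 the KO count was 1089 (733 rose, 356 fell), with 1 DMSO library left and assumed to vary like the others, the interaction gave 192 at 2-fold, and r was 0.181. With protein-coding genes only, and so fewer genes tested, 79 genes were called at 2-fold in WT and 68 for the interaction, and r was 0.298. With limma-voom 48 genes were called at 2-fold in KO, and the cause was not tested.

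Leaving out 1 library of the groups compared at a time gave 5886 to 6926 genes for WT, 1896 to 2460 for KO, 3474 to 4563 for the interaction, 11080 to 11173 for KO against WT with DMSO and 11159 to 11306 with Dox. Leaving out 1 library of another group gave 6545 to 6742 for WT, 2574 to 3469 for KO, 11247 to 11398 with DMSO and 11319 to 11395 with Dox, where 3469 was without WT Dox replicate 1. At 2-fold the ranges over libraries of the groups compared were 195 to 207, 27 to 32, 80 to 191, 3458 to 3513 and 3449 to 3516, where 191 was without KO DMSO replicate 1 and 80 without KO DMSO replicate 3. The range of r was 0.229 to 0.378, with 0.229 without KO DMSO replicate 1. Genes that fell in KO went from 1278 to 831 without KO DMSO replicate 1, 766 without KO Dox replicate 1 and 836 without KO Dox replicate 2. DESeq2 called 6013, 2285, 3549, 11062 and 11146 genes in the order above, and limma-voom 6647, 2749, 4022, 11266 and 11339. With the replicate number as a block the counts were 6664, 2679, 4050, 11296 and 11355, and among named genes and lists 2 calls changed: the interferon-stimulated genes passed for the interaction (mean -0.28, camera adjusted p = 0.039) and mt-Cytb in KO (-0.10, adjusted p = 0.04, edgeR). Libraries with the same number had residual correlations of -0.108 to 0.112, with 1 of 18 over 0.1. Libraries with different numbers were not compared in this way, so these values do not settle whether the numbers pair the samples. A filter of genes with no counts alone removed 0 genes, as the main filter did, and the calls were the same. The table's omission of genes with low counts, at a depth of at least 44476039 reads, limits which genes were measured.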

Other observations

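The genes in this part were chosen after their values were seen. All 18 measured replication-dependent histone genes were at least 2-fold higher in KO than in WT with DMSO, with a median log2 fold change of 3.06 (1.43 to 5.56), and also with Dox, with a median of 3.51 (1.59 to 6.63). Hist1h1c, a linker histone gene (chromosome 13, positions 23738808 to 23740367), had 19.6 ± 0.445 CPM in WT DMSO and 245 ± 6.56 in KO DMSO (SD, n = 3 each), a log2 fold change of 3.64 ± 0.0375. Hist1h2bc went from 12.9 to 132 CPM and Hist2h3c2 from 0.976 to 31.9. Most transcripts of such genes lack a poly(A) tail and the libraries were made from polyadenylated RNA. The rise of these 18 genes therefore covers polyadenylated transcripts alone and does not measure all histone transcripts. Genes with low counts had also been left out of the deposited data. A histone gene near that limit in WT, such as Hist2h3c2, could thus be measured only because it was high in KO. The shared direction of the 18 genes may partly come from this selection. Near-identical copies also share reads, so single values are uncertain.

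Long noncoding RNAs differed as well. Neat1, the scaffold of paraspeckles, was at 182 ± 9.06 CPM in WT DMSO and 1876 ± 44.3 in KO DMSO (log2 fold change 3.37 ± 0.0287), and Malat1, a nuclear speckle RNA, was at 172 ± 13.8 and 900.1 ± 80.4 (2.39 ± 0.188). Xist, which silences an X chromosome, was at 1431 ± 64.7 and 2925 ± 55.2 (1.03 ± 0.0676). H19, an imprinted RNA (chromosome 7, positions 142575529 to 142578143), had 243 to 253 counts in the WT DMSO libraries and 0 in every KO library, so it was at least 84.7-fold lower with DMSO and at least 167-fold lower with Dox against a floor of 3 counts per library. Of the other genes without counts in KO DMSO, 8 in all, Tgfbi, a secreted matrix protein gene, was at least 263-fold lower (749 to 778 counts in WT) and Sparcl1, a relative of the matrix gene Sparc, at least 58.3-fold lower. In KO Dox 11 genes had no counts.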
